A study of Capra hircus with 72 samples.

How the data were processed

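RNA was sequenced from 4 brain regions of goats (Capra hircus, female) kept for 14 days under 1 of 3 conditions. The regions were the medial prefrontal cortex (mPFC), the nucleus of the solitary tract (NTS), the ventral respiratory column (VRC) and the retrotrapezoid nucleus (RTN). The conditions were room air, mild chronic hypercapnia (14 days at 6% CO2) and moderate chronic hypercapnia (7 days at 6% CO2, then 7 days at 8%). Per the labels each region and condition has 6 replicates, which gives 72 libraries in 12 groups. The series description gives 6 animals per condition, which makes 18.

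The deposited table holds counts, which the authors gave as raw whole numbers per gene, for 21343 protein-coding goat genes in 72 columns. It also holds deposited rpkm values in another 72 columns. The library size implied by the rpkm values was 1.0047 to 1.0069 times the sum of the count column, so the authors applied no further scaling factor. A length column in the deposited file, of the unit other, gives the gene model length in bases. The authors' notes name FastQC, Trimmomatic, STAR, featureCounts and edgeR. Their versions, the genome build and the annotation release are not given in the sources used here. In 89.7% of the genes the span from start to end is shorter than the length given, so only chromosomes are printed. A symbol is missing for 6643 genes. The counting of reads shared by near-identical genes is not stated, so values of multigene families such as ribosomal proteins and histocompatibility genes are uncertain.

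Library totals ran from 12.84 to 31.88 M counts, with a median of 19.3 M, and the 10 most abundant genes took 4.11% to 12.82% of a library. No 2 libraries of a group were near copies: the chi-square per degree of freedom between them was 15.3 to 216.31. Same-numbered libraries of 1 condition deviated together across regions. The median r of their deviations was 0.233 over 108 pairs, with 92 over 0.1, and 69 of 72 libraries lay closest to their own number. The labels do not say that a number marks an animal, so values per animal rest on that reading. Same-numbered libraries of different conditions had a median r of 0.02, with 22 of 72 pairs over 0.1, so the numbers were not taken to pair conditions.

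All tests used the counts. In each region the 18 libraries were fitted together with edgeR 4.0.16 (R 4.3.3): filterByExpr with a minimum count of 10, TMM factors, and the quasi-likelihood F-test, adjusted by Benjamini-Hochberg at 0.05 over the genes tested. Errors of log2 fold changes are standard errors (SE) and those of CPM, counts scaled to a common library size, are standard deviations (SD). Each hypercapnia condition was compared with room air, and moderate with mild. Whether a response differed among regions was tested on all 72 libraries, taken as independent, with 3 degrees of freedom. It was tested again with the replicate of each condition, read as an animal, as a block.

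Gene lists were fixed before the data were examined: 23 of pathways and 18 of cell types or tissues, 41 in all. Those with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Members were also adjusted over the list alone. The same test for moderate against mild was added later. Camera compares a list with the other genes, and a call at the preset correlation takes the members as nearly independent.

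Genes to be named were chosen by a rule. In each direction it takes the 6 largest changes at an adjusted p under 0.05 with a symbol, a mean of at least 5 CPM and at least 5 of 6 treated libraries on the called side of the room air median. Of each list it takes up to 4 members called over all genes or over the list alone, and for a called list with no such member the 2 of smallest p. Where 5 or fewer genes are called it takes all of them. For the tests among regions it takes the 5 genes of smallest p. Some genes that the rule picks are left out of the text. Any other gene named in a comparison is said to have been chosen after its values were seen.

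The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, the replicate number as a block, limma with quality weights, a fit of the 2 groups alone, and the mean log2 CPM of the myelin list as a covariate. Within a region the replicate block joins same-numbered libraries of different conditions. These were not taken to be paired, so it does not block by animal. Fits without single libraries (in each region the one of lowest quality weight, mild replicate 3 and moderate replicate 3), and edgeR's newer form of the quasi-likelihood fit, were added after the data had been seen. On simulated data edgeR called 29.9% to 55.2% of genes changed 1.5-fold and 64.2% to 77.6% of those changed 2-fold. Of those changed 4-fold it called 93.9% to 98.5%. DESeq2 called 40.3% to 65.7% of genes changed 1.5-fold. Beside these changed genes, 66 or 67 at each fold, DESeq2 made 20 to 37 false calls and edgeR 4 to 12. False calls can grow in number with true ones, so these are not rates for unchanged groups. In a simulated group without changes edgeR called 0, and DESeq2 was not counted there. The simulation drew each gene independently and set no library apart, so these shares may be higher than in the real libraries. The rpkm columns were not tested, since they carry the same counts.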

Results

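RNA was measured in the medial prefrontal cortex (mPFC) and in 3 brainstem regions that take part in breathing: the nucleus of the solitary tract (NTS), the ventral respiratory column (VRC) and the retrotrapezoid nucleus (RTN). Goats breathed room air, air with 6% CO2 for 14 days (mild chronic hypercapnia), or 6% for 7 days and then 8% for 7 days (moderate). Each of the 12 groups held 6 libraries. Mean totals per group ran from 16.88 ± 2.3 M counts (SD, n = 6) in moderate NTS to 21.3 ± 6.15 M in moderate RTN, and single libraries from 12.84 to 31.88 M.

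Marker genes told the regions apart in room air. SLC17A7, a glutamate transporter of cortical neurons, stood at 749 ± 180 CPM (SD, n = 6) in mPFC. It was at 57.7 ± 19.8 CPM in VRC, 10.6 ± 4.98 in RTN and 6.25 ± 3.69 in NTS. The hindbrain gene HOXA4 stood at 44.3 ± 8.9 CPM in NTS, 34.4 ± 5.79 in VRC, 8.46 ± 3.61 in RTN and 0.0337 ± 0.0394 in mPFC. TPH2, which makes serotonin, was at 80.4 ± 22.3 CPM in RTN and 10.5 ± 7.56 in VRC. SLC6A5, the glycine transporter of inhibitory neurons, was at 126 ± 15.4 CPM in VRC, 88 ± 24 in RTN and 50.4 ± 19.4 in NTS.

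**Figure D1:**
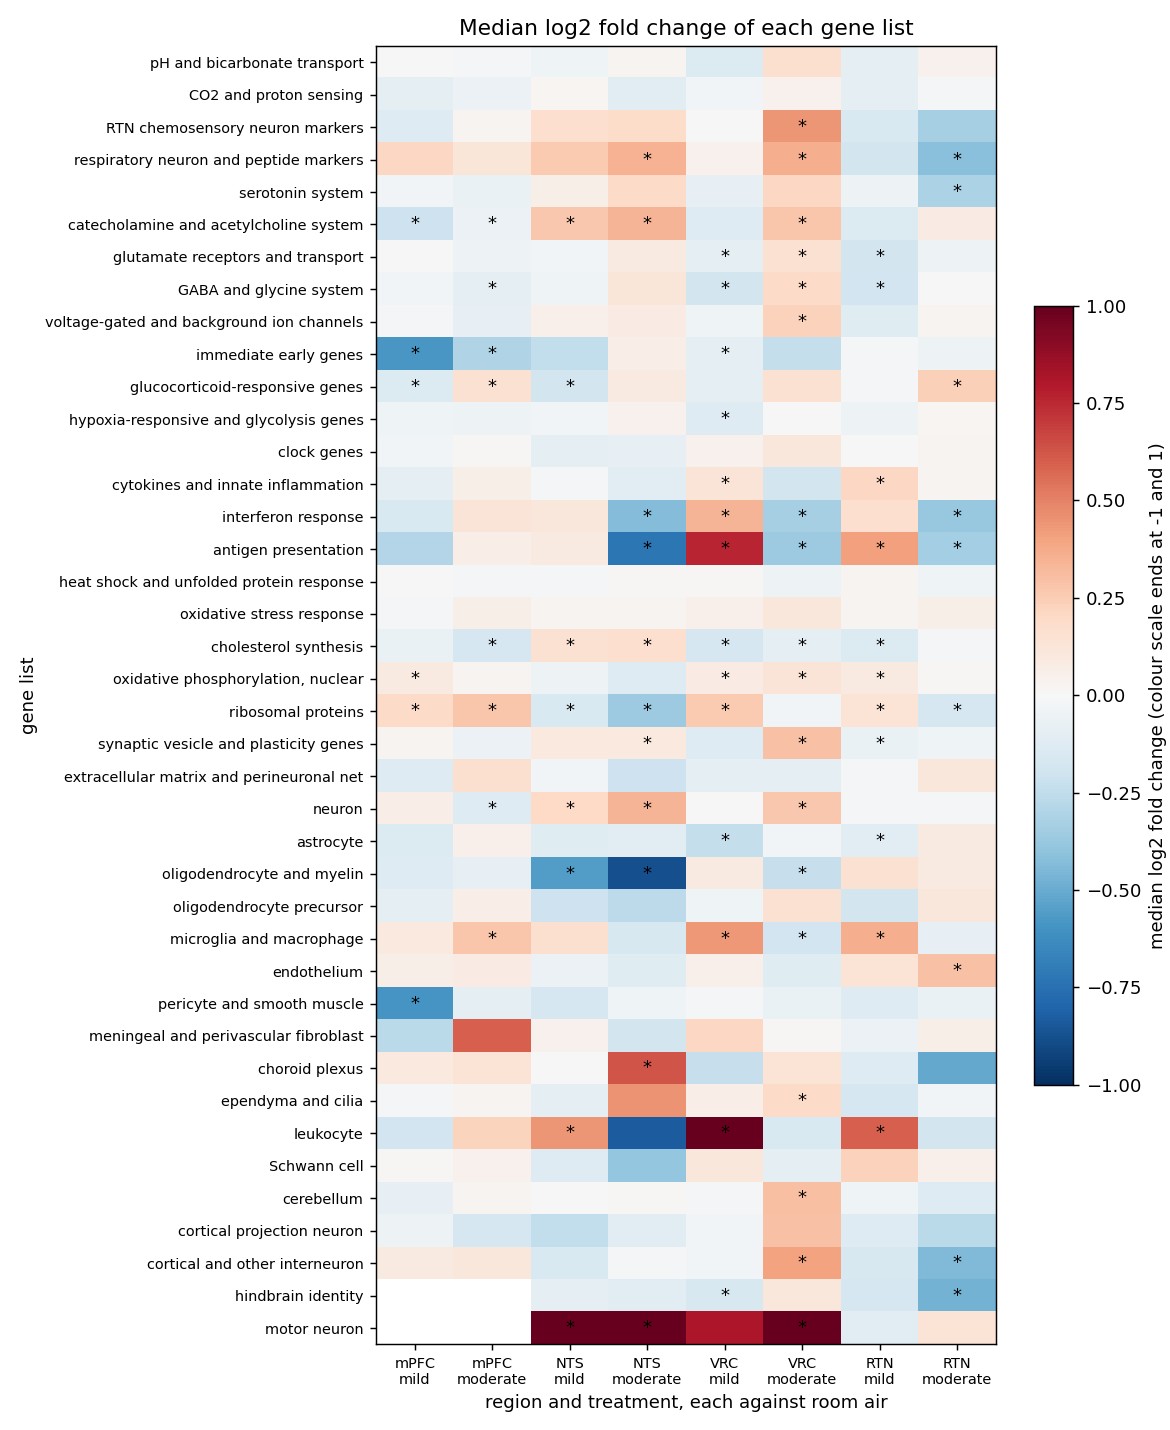
Median log2 fold change of each gene list (vertical axis) in each region under mild or moderate hypercapnia against room air (horizontal axis), with a star for a list called at the preset correlation. Immediate early genes stand at -0.58 in mPFC under mild hypercapnia and the myelin list at -0.88 in NTS under moderate hypercapnia.

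The comparison of mild hypercapnia with room air in mPFC asks how a cortical region differed after 14 days at 6% CO2. Immediate early genes, which are switched on within minutes of stimulation, fell: their median log2 fold change was -0.58 and 24 of 26 members were negative (adjusted p = 7.39e-21). This list was also called with an estimated correlation (adjusted p = 0.032, not corrected over the comparisons), and 8 members passed when adjusted over the list alone. Among them NR4A1, a nuclear receptor, fell from 130 ± 41.4 to 67.3 ± 20.2 CPM (SD, n = 6; log2 -0.95 ± 0.30), and JUNB, a subunit of the transcription factor AP-1, from 103 ± 30.7 to 62 ± 16.3. DUSP1, a phosphatase that inactivates MAP kinases, fell from 197 ± 49 to 113 ± 35.8 CPM, and ATF3, a stress-induced transcription factor, from 0.871 ± 0.289 to 0.219 ± 0.115 CPM. All 4 were below the room air median in 6 of 6 mild libraries. Since genes of this list respond within minutes, the state of the animals shortly before death is not separated here from 14 days of CO2.

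Pericyte and smooth muscle markers fell with them in mPFC (median -0.59, 11 of 11 negative, adjusted p = 5.96e-05, and adjusted p = 0.49 with an estimated correlation). MYH11, smooth muscle myosin, was at 111 ± 127 CPM in room air and 38.8 ± 25.7 in mild hypercapnia, so its spread exceeded its mean. Ribosomal proteins (median 0.19, 24 of 26 positive, adjusted p = 0.000791) and nuclear genes of oxidative phosphorylation (median 0.09, 25 of 28 positive, adjusted p = 0.000542) rose, each with adjusted p = 0.93 with an estimated correlation. The catecholamine and acetylcholine list fell (median -0.21, adjusted p = 0.0295, and adjusted p = 0.49 with an estimated correlation). So did glucocorticoid-responsive genes (median -0.14, adjusted p = 0.0368, and adjusted p = 0.91 with an estimated correlation), where DUSP1 passed adjusted over the list alone. Over all 15403 genes edgeR called 0, with 532 at an unadjusted p under 0.05 where chance gives 770, limma with quality weights called 0 and DESeq2 called 3. Of these 3, chosen after their values were seen, APOLD1 (ENSCHIG00000008149, chromosome 5), an early response gene of endothelium, had the lowest edgeR adjusted p, 0.11 (log2 -2.39 ± 0.39). It stood at 8.7 ± 5.97 CPM in room air and 1.65 ± 0.291 in mild hypercapnia. CSRNP1 had a log2 fold change of -0.78 ± 0.14 (adjusted p = 0.26), and the other was ENSCHIG00000020422, a gene without a symbol. With mild replicate 3 left out, 12 lists were called in place of 6, and the ribosomal proteins (adjusted p = 0.061) and glucocorticoid-responsive genes (0.061) were not. Mild replicate 5 stood apart in the ribosomal proteins score (5.75 in mean log2 CPM, the others 6.82 to 7.04), and without it the ribosomal list had adjusted p = 5e-20, the glucocorticoid list 0.15 and the catecholamine list 0.07. The count at an unadjusted p under 0.05 was 1066 without mild replicate 5 and 1077 in limma with quality weights, in place of 532. A count below chance thus depended on the fit.

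Moderate hypercapnia was compared with room air in the same cortical region. ANGPTL4, a secreted regulator of lipoprotein lipase, rose from 13.3 ± 1.72 to 18.8 ± 1.76 CPM (SD, n = 6; log2 0.49 ± 0.12, adjusted p = 0.0081, adjusted over the list alone). ZBTB16, a transcription factor induced by glucocorticoids, rose from 20.3 ± 2.65 to 27.9 ± 4 CPM. The glucocorticoid-responsive list that holds both rose (median 0.15, 12 of 18 positive, adjusted p = 0.00288, and adjusted p = 0.51 with an estimated correlation). The pericyte genes KCNJ8, a potassium channel subunit, and RGS5, a regulator of G protein signalling, fell to 17.1 ± 2.5 from 23.3 ± 4.42 CPM and to 38.8 ± 9.38 from 58.1 ± 21.3, with adjusted p = 0.026 and 0.049, adjusted over the list alone, while the pericyte list was not called (median -0.09, adjusted p = 0.292).

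Immediate early genes fell again in mPFC (median -0.30, 20 of 26 negative, adjusted p = 6.97e-08, and adjusted p = 0.51 with an estimated correlation), with ARC at 119 ± 49.7 CPM in room air and 72.1 ± 27.8 in moderate hypercapnia. Cholesterol synthesis genes fell (median -0.17, 21 of 22 negative, adjusted p = 6.61e-09, and adjusted p = 0.51 with an estimated correlation). Ribosomal proteins rose (median 0.28, 26 of 26 positive, adjusted p = 6.61e-09, and adjusted p = 0.71 with an estimated correlation). Microglia and macrophage markers rose (median 0.28, 15 of 17 positive, adjusted p = 0.00288, and adjusted p = 0.77 with an estimated correlation), with TMEM119 at 9.75 ± 1.35 and 13.2 ± 3.18 CPM. Neuron markers (median -0.13, adjusted p = 0.0052, and adjusted p = 0.71 with an estimated correlation) and the GABA and glycine list (median -0.10, adjusted p = 0.0125, and adjusted p = 0.77 with an estimated correlation) fell. The catecholamine and acetylcholine list fell too (median -0.06, adjusted p = 0.0471, and adjusted p = 0.51 with an estimated correlation). Without moderate replicate 3, which held 82.9 CPM of FKBP5, the glucocorticoid (adjusted p = 0.12) and catecholamine (0.13) lists lost their calls, and without mild replicate 5 the catecholamine list did (0.051). No gene passed over all 15403: edgeR called 0, with 324 at an unadjusted p under 0.05, where chance gives 770. DESeq2 and limma with quality weights also called 0. Without mild replicate 5, 502 genes had an unadjusted p under 0.05 in place of 324.

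In NTS, where afferents of lung, heart and carotid body end, the neuropeptide gene SST rose after mild hypercapnia from 562 ± 264 to 1120 ± 373 CPM (SD, n = 6; log2 0.99 ± 0.28, adjusted p = 0.048, adjusted over the list alone, 6 of 6 libraries). FOXP2, a transcription factor, fell from 4.89 ± 2.83 to 2.14 ± 0.852 CPM (log2 -1.18 ± 0.36, adjusted p = 0.027, adjusted over the list alone). Motor neuron markers rose (median 1.07, 6 of 6 positive, adjusted p = 0.000203). None of them passed adjusted over the list alone, and SLC5A7 stood at 54.9 ± 54.5 CPM in room air and 117 ± 60 in mild hypercapnia. The catecholamine and acetylcholine list (median 0.27, adjusted p = 0.00492), neuron markers (median 0.20, adjusted p = 0.0082), cholesterol synthesis genes (median 0.15, adjusted p = 0.00987) and leukocyte markers (median 0.44, adjusted p = 0.0102) rose too. All 5 lists had adjusted p = 0.73 with an estimated correlation. Myelin markers fell beside them (median -0.56, 10 of 11 negative, adjusted p = 0.00099, and adjusted p = 0.73 with an estimated correlation), with ERMN at 406 ± 300 CPM in room air and 230 ± 85.8 in mild hypercapnia. Glucocorticoid-responsive genes (median -0.18, adjusted p = 0.0186, and adjusted p = 0.73 with an estimated correlation) and ribosomal proteins (median -0.15, 26 of 26 negative, adjusted p = 0.00256, and adjusted p = 0.78 with an estimated correlation) fell. Of 15418 genes edgeR called 0, with 718 at an unadjusted p under 0.05, limma with quality weights called 0 and DESeq2 called 5. The 5, chosen after their values were seen, were APOLD1 (log2 -2.33 ± 0.45), SH2D4B (log2 1.89 ± 0.40) and 3 genes without a symbol, ENSCHIG00000000053, ENSCHIG00000014169 and ENSCHIG00000002879. Without room air replicate 1 the ribosomal proteins changed sign (adjusted p = 0.43), and the catecholamine (0.22), neuron (0.06), myelin (0.072) and glucocorticoid (0.072) lists lost their calls. Without mild replicate 3 the leukocyte (0.068) and glucocorticoid (0.083) lists did, and with the myelin score as a covariate 3 lists were called in place of 8. The count at an unadjusted p under 0.05, where chance gives 771, also depended on the fit. It was 436 with that covariate, 1166 with the replicate number as a block and 2581 in limma with quality weights.

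Moderate hypercapnia in NTS gave the 1 gene that edgeR called against room air in any region. THSD1 (ENSCHIG00000016392, chromosome 12), a membrane protein of endothelium, fell from 25.5 ± 3.57 to 14.9 ± 1.55 CPM (SD, n = 6; log2 -0.78 ± 0.12, adjusted p = 0.046, 6 of 6 libraries). KCNJ10 (ENSCHIG00000001309, chromosome 3), a glial potassium channel placed among the CO2 and proton sensing genes, fell from 110 ± 16 to 68.6 ± 13 CPM (log2 -0.68 ± 0.15, adjusted p = 0.0045, adjusted over the list alone). Myelin markers fell (median -0.88, 10 of 11 negative, 9 passing adjusted over the list alone, adjusted p = 5.65e-06, and adjusted p = 0.51 with an estimated correlation). UGT8, an enzyme of myelin lipid synthesis, fell from 122 ± 77.6 to 55.6 ± 32.7 CPM, and ASPA, which breaks down N-acetylaspartate in oligodendrocytes, from 30.3 ± 9.02 to 19.8 ± 4.31.

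Other list members passed in NTS when adjusted over the list alone. Lower were GJB1, a gap junction protein of oligodendrocytes (21 ± 15.9 to 7.12 ± 3.77 CPM), SLC9A9, an endosomal proton exchanger (8.67 ± 4.73 to 4.51 ± 0.65), and ADM, a vasodilator peptide (9.26 ± 3.28 to 4.26 ± 1.6). CCN1, a matricellular protein, fell from 19.4 ± 4.46 to 10.9 ± 1.98 CPM, and SGK1, a kinase induced by steroids, from 159 ± 39.1 to 118 ± 11.2. Higher were FKBP5, a chaperone induced by glucocorticoids (13.2 ± 4.48 to 30.6 ± 19 CPM), the peptide gene VIP (1.41 ± 0.752 to 8.4 ± 7.89) and the serotonin receptor HTR4 (1.32 ± 0.173 to 2.44 ± 0.598). Ribosomal proteins fell (median -0.36, 26 of 26 negative, 18 passing adjusted over the list alone, adjusted p = 1.61e-12, and adjusted p = 0.51 with an estimated correlation), RPS10 from 78.1 ± 24.1 to 56.4 ± 3.69 CPM. Antigen presentation genes fell (median -0.72, 9 of 9 negative, adjusted p = 0.00122, and adjusted p = 0.51 with an estimated correlation), HLA-DOB from 21.4 ± 14.5 to 9.84 ± 2.29 CPM. Interferon response genes fell as well (median -0.43, 22 of 24 negative, adjusted p = 7.31e-05, and adjusted p = 0.51 with an estimated correlation).

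The lists that rose in NTS under moderate hypercapnia were those of motor neurons (median 1.08, adjusted p = 0.00197), neurons (0.34, 0.0018), synaptic vesicles and plasticity (0.10, 0.00282), catecholamines and acetylcholine (0.34, 0.00422) and cholesterol synthesis (0.17, 0.00645). Respiratory neuron and peptide markers (0.35, 0.0169) and choroid plexus markers (0.63, 0.0451) rose too, and all 7 had adjusted p = 0.51 with an estimated correlation. No motor neuron marker passed adjusted over the list alone, and SLC5A7 stood at 54.9 ± 54.5 CPM in room air and 142 ± 102 in moderate hypercapnia. Among 15418 genes, 2073 had an unadjusted p under 0.05, where chance gives 771, DESeq2 called 22 and limma with quality weights 3. The THSD1 call was lost without room air replicate 1 (adjusted p = 0.079), without moderate replicate 3 (0.13), with the replicate number as a block (0.11), with the myelin score as a covariate (0.57), in a fit of the 2 groups alone (0.14) and in edgeR's newer form of the fit (0.05). Without room air replicate 1 the count at an unadjusted p under 0.05 was 1087 and the catecholamine (adjusted p = 0.091) and choroid plexus (0.093) lists lost their calls, as did respiratory peptides without moderate replicate 3 (0.053). With the myelin score as a covariate that count was 531, with 5 lists called in place of 11 and the cholesterol synthesis list reversed (adjusted p = 0.86).

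In VRC, the column of neurons that shapes the breathing rhythm, leukocyte markers rose after mild hypercapnia (median 1.42, 9 of 9 positive, 7 passing adjusted over the list alone, adjusted p = 1.04e-06, and adjusted p = 0.54 with an estimated correlation). The median was 0.54 without mild replicate 3, which held 17.6 CPM of CD4 where the other 5 held 0.467 to 3.99. CD4 went from 0.977 ± 0.681 to 4.69 ± 6.43 CPM (SD, n = 6), and CD3D, a part of the T cell receptor complex, from 0.369 ± 0.214 to 2.49 ± 2.99. COL6A3 (ENSCHIG00000018312, chromosome 3), a collagen chain, rose from 24.4 ± 8.59 to 52.8 ± 4.38 CPM (log2 1.12 ± 0.21, adjusted p = 0.00083, adjusted over the list alone). VEGFA (ENSCHIG00000009242, chromosome 23), the endothelial growth factor induced by low oxygen, fell from 43.7 ± 6.05 to 26.1 ± 5.44 CPM (log2 -0.75 ± 0.16, adjusted p = 0.0024, adjusted over the list alone, 6 of 6 libraries).

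Microglia and macrophage markers rose in VRC (median 0.43, 16 of 16 positive, adjusted p = 1.04e-06), as did antigen presentation genes (0.76, 9 of 9, 0.000108), both with adjusted p = 0.54 with an estimated correlation. Interferon response genes (median 0.34, adjusted p = 0.00204, and adjusted p = 0.76 with an estimated correlation) and cytokines (median 0.13, adjusted p = 0.00588, and adjusted p = 0.69 with an estimated correlation) rose. So did ribosomal proteins (median 0.26, adjusted p = 4.3e-07, and adjusted p = 0.71 with an estimated correlation) and oxidative phosphorylation genes (median 0.08, adjusted p = 0.045, and adjusted p = 0.89 with an estimated correlation). Cholesterol synthesis genes fell (median -0.17, 22 of 22 negative, adjusted p = 4.3e-07) with the hypoxia and glycolysis list of VEGFA (-0.13, 18 of 24, 0.000533), both with adjusted p = 0.24 with an estimated correlation. The GABA and glycine list (median -0.18, 23 of 26 negative, adjusted p = 4e-05, and adjusted p = 0.54 with an estimated correlation) fell. Glutamate genes (median -0.09, adjusted p = 0.0277) and hindbrain identity genes (-0.16, 0.0277) fell, both with adjusted p = 0.69 with an estimated correlation. Immediate early genes (median -0.10, adjusted p = 0.0488) and astrocyte markers (-0.24, 0.045) fell, both with adjusted p = 0.71 with an estimated correlation.

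Over 15302 genes in VRC under mild hypercapnia edgeR called 0, with 953 at an unadjusted p under 0.05, where chance gives 765. That count was 704 without mild replicate 3, 1357 with the replicate number as a block and 1544 in limma with quality weights. A fit of the 2 groups alone called 1 gene, limma with quality weights 2 and DESeq2 27. IL20RB, a cytokine receptor subunit chosen after its values were seen, was called by DESeq2 and stood at 0.403 ± 0.137 CPM in room air and 8.66 ± 6.29 in mild hypercapnia (SD, n = 6; edgeR adjusted p = 0.27). Without mild replicate 3, 8 lists were called in place of 14, and the antigen presentation, interferon and cytokine lists lost their calls (adjusted p = 0.084, 0.42 and 0.31), as did the glutamate, astrocyte and hindbrain lists (0.22, 0.55 and 0.16). Without moderate replicate 1, which shares the fit, the immediate early gene (0.055) and astrocyte (0.053) lists lost theirs. With the replicate number as a block 12 lists were called in place of 14.

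Moderate hypercapnia was compared with room air in the same respiratory column. VEGFA fell from 43.7 ± 6.05 to 26.3 ± 5.32 CPM (SD, n = 6; log2 -0.74 ± 0.15, adjusted p = 0.0029, adjusted over the list alone, 6 of 6 libraries), close to its mild level. NPPC, the C-type natriuretic peptide, rose from 54.4 ± 13.4 to 94.2 ± 34.7 CPM, and ZBTB16 from 11.9 ± 2.32 to 19.6 ± 5.96, each passing adjusted over the list alone. So did FKBP5, which rose from 10.6 ± 2.45 to 31.9 ± 35.5 CPM with 103 CPM in moderate replicate 3, and CCDC153, a gene of motile cilia (4.55 ± 1.68 to 8.45 ± 3.6). ASPA fell from 46.6 ± 7.98 to 32.1 ± 5.72 CPM, and MYH11 from 60.8 ± 9.1 to 44.5 ± 7.27, again adjusted over the list alone.

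In this comparison 18 lists were called in VRC, 13 higher and 5 lower, and 0 with an estimated correlation. With the myelin score as a covariate 13 lists were called. Without moderate replicate 1, of quality weight 0.31, 12 were called, and 9 of the 18 lost their call: oxidative phosphorylation (adjusted p = 0.18), ependyma (0.13), neuron (0.091), RTN chemosensory (0.086), interneuron (0.084), microglia (0.082), cerebellum (0.076), motor neuron (0.067) and cholesterol synthesis (0.066). Without moderate replicate 3 the glutamate (0.12), microglia (0.14) and cerebellum (0.064) lists lost theirs. Synaptic vesicle and plasticity genes rose (median 0.29, 28 of 32 positive, adjusted p = 2.43e-06) with ion channels (0.23, 27 of 31, 0.000832), GABA and glycine genes (0.19, 22 of 26, 0.00273), neuron markers (0.27, 12 of 12, 0.00327) and motor neuron markers (1.08, 6 of 6, 0.00925). Respiratory peptides (0.36, 0.0058), the catecholamine and acetylcholine list (0.28, 0.0058), RTN chemosensory markers (0.44, 0.0195), interneuron markers (0.40, 0.0233) and glutamate genes (0.15, 0.041) rose too. Cerebellar and ependymal markers (medians 0.30 and 0.19, both adjusted p = 0.034) rose as well. Interferon (-0.33, 0.000258), myelin (-0.23, 0.000359), cholesterol synthesis (-0.09, 0.00778) and antigen presentation (-0.36, 0.0229) lists fell. These 16 lists had adjusted p = 0.49 with an estimated correlation. Oxidative phosphorylation rose (median 0.13, adjusted p = 0.00189, and adjusted p = 0.56 with an estimated correlation) and microglia markers fell (median -0.19, adjusted p = 0.041, and adjusted p = 0.59 with an estimated correlation). Of 15302 genes edgeR called 0, with 867 at an unadjusted p under 0.05, limma with quality weights called 0, a fit of the 2 groups alone 1 and DESeq2 10. With the myelin score as a covariate 523 genes had an unadjusted p under 0.05, where chance gives 765. That count was 650 without moderate replicate 3 and 1360 in limma with quality weights.

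In RTN, a site of central CO2 sensing, 3 genes of microglia and T cells rose after mild hypercapnia when adjusted over their lists alone. CX3CR1, the fractalkine receptor of microglia, rose from 30.9 ± 3.61 to 47.7 ± 5.3 CPM (SD, n = 6; log2 0.63 ± 0.18, adjusted p = 0.04, adjusted over the list alone), and P2RY12, a microglial purine receptor, from 23 ± 4.43 to 32.7 ± 6.96. CD2, a T cell adhesion molecule, rose from 0.423 ± 0.364 to 1.86 ± 0.59 CPM (adjusted p = 5e-04, adjusted over the list alone). These 3 genes lay on the called side of the room air median in 6 of 6 libraries.

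As groups, microglia (median 0.36, 16 of 16 positive, adjusted p = 5.51e-08) and antigen presentation genes (0.41, 9 of 9, 0.000337) rose in RTN, both with adjusted p = 0.37 with an estimated correlation, and leukocyte markers rose (0.60, 8 of 8, adjusted p = 8.92e-07, and adjusted p = 0.14 with an estimated correlation). Cytokines rose (median 0.21, adjusted p = 0.00669, and adjusted p = 0.53 with an estimated correlation), with CCL2 at 9.98 ± 4.44 and 51.2 ± 61.2 CPM. Ribosomal proteins (median 0.14, 25 of 26 positive, adjusted p = 5.51e-08, and adjusted p = 0.43 with an estimated correlation) and oxidative phosphorylation genes (median 0.09, adjusted p = 1.12e-05, and adjusted p = 0.37 with an estimated correlation) rose. The GABA and glycine list (median -0.19, 22 of 26 negative, adjusted p = 4.28e-05) and glutamate genes (-0.18, 26 of 31, 0.00132) fell, both with adjusted p = 0.14 with an estimated correlation. Cholesterol synthesis genes fell (median -0.14, adjusted p = 0.000827, and adjusted p = 0.37 with an estimated correlation). Synaptic vesicle genes (median -0.07, adjusted p = 0.0268) and astrocyte markers (-0.11, 0.029) fell, both with adjusted p = 0.53 with an estimated correlation. Without mild replicate 3 the synaptic vesicle (adjusted p = 0.1) and astrocyte (0.36) lists lost their calls. Among 15343 genes edgeR called 0, with 1011 at an unadjusted p under 0.05, where chance gives 767. Limma with quality weights called 1 and DESeq2 17.

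After moderate hypercapnia in RTN, ANGPTL4 (ENSCHIG00000023643, chromosome 7) rose from 7.62 ± 1.03 to 15.3 ± 5.25 CPM (SD, n = 6; log2 1.00 ± 0.21, adjusted p = 0.0028, adjusted over the list alone, 6 of 6 libraries). KL, the klotho gene of choroid plexus, fell from 9.3 ± 3.92 to 4.38 ± 2.84 CPM, and ZIC1, a hindbrain and cerebellar transcription factor, from 0.545 ± 0.245 to 0.203 ± 0.075, each passing adjusted over the list alone. Glucocorticoid-responsive genes rose (median 0.24, 15 of 18 positive, adjusted p = 2.52e-05, and adjusted p = 0.54 with an estimated correlation). Ribosomal proteins (median -0.17, 26 of 26 negative, adjusted p = 2.79e-09), interferon response genes (-0.38, 20 of 24, 1.49e-05), respiratory neuron and peptide markers (-0.42, 14 of 18, 0.000163) and hindbrain identity genes (-0.47, 12 of 14, 0.00152) fell, each with adjusted p = 0.54 with an estimated correlation.

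The serotonin list (median -0.32, adjusted p = 0.0125) and interneuron markers (-0.44, 0.0191) fell in RTN as well, both with adjusted p = 0.54 with an estimated correlation. Among the peptides, NPY was at 5.56 ± 3.05 CPM in room air and 1.83 ± 1.65 in moderate hypercapnia, and CRH at 4.53 ± 2.29 and 1.54 ± 0.833 (SD, n = 6). Endothelial markers rose (median 0.29, 12 of 14 positive, adjusted p = 0.0035, and adjusted p = 0.64 with an estimated correlation), and antigen presentation genes fell (median -0.34, 9 of 9 negative, adjusted p = 0.0158, and adjusted p = 0.61 with an estimated correlation). The endothelium call was lost without moderate replicate 5 (adjusted p = 0.46), the antigen presentation (0.069) and interneuron (0.12) calls without moderate replicate 3, and the serotonin call without either (0.068 and 0.088). Of the 15343 genes edgeR called 0, with 1132 at an unadjusted p under 0.05, where chance gives 767. Limma with quality weights called 0 there, a fit with the myelin score as a covariate 3 and DESeq2 27.

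Lists chosen for CO2 sensing and acid handling were called in none of the 8 comparisons with room air: the lowest adjusted p was 0.313 for CO2 and proton sensing and 0.111 for pH and bicarbonate transport. RTN chemosensory neuron markers were called in VRC under moderate hypercapnia (adjusted p = 0.0195, and adjusted p = 0.49 with an estimated correlation, or 0.086 without VRC moderate replicate 1). In RTN they were not called (median -0.33, adjusted p = 0.33), and the difference between the 2 regions was not tested for this list.

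**Figure D2:**
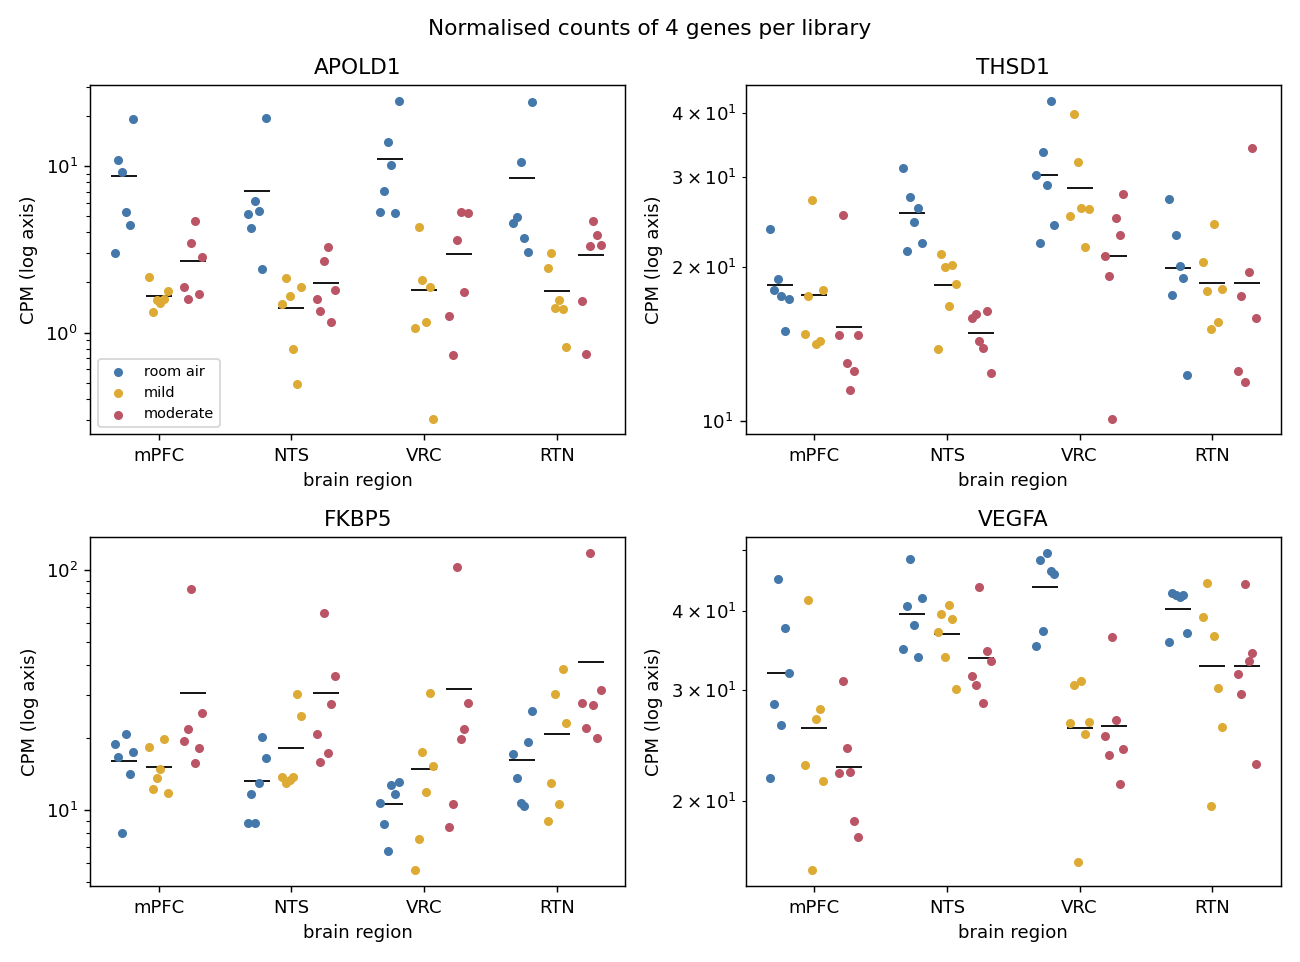
CPM (log axis) of APOLD1, THSD1, FKBP5 and VEGFA in each library, by region and condition, with a black bar at the group mean. APOLD1 averages 8.7 CPM in room air and 1.65 under mild hypercapnia in mPFC, and FKBP5 reaches 118 CPM in 1 moderate RTN library.

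Moderate was compared with mild hypercapnia to ask whether the level of CO2 mattered. Immune lists were lower under moderate hypercapnia in the 3 brainstem regions, and 3 of them were higher in mPFC, at the preset correlation and not with an estimated one. Antigen presentation genes fell by medians of -0.84 in NTS (adjusted p = 4.85e-10, and adjusted p = 0.46 with an estimated correlation), -1.17 in VRC (9.24e-07, and adjusted p = 0.28 with an estimated correlation) and -0.78 in RTN (8.86e-09, and adjusted p = 0.13 with an estimated correlation), with 9 of 9 members negative in each. Interferon response genes fell in the same regions (medians -0.48, -0.71 and -0.44, with adjusted p = 0.46, 0.28 and 0.23 with an estimated correlation), and leukocyte markers fell (-1.12, -1.62 and -0.88, with adjusted p = 0.46, 0.29 and 0.13 with an estimated correlation). In mPFC antigen presentation (median 0.35, adjusted p = 0.0451), interferon response (0.24, 0.0143) and microglia (0.24, 0.0261) lists rose, each with adjusted p = 0.62 with an estimated correlation. The mild VRC group includes replicate 3, without which its leukocyte median against room air was 0.54 in place of 1.42. Glucocorticoid-responsive genes rose in mPFC (0.28, adjusted p = 9.14e-07), NTS (0.20, 0.00129), VRC (0.20, 0.0257) and RTN (0.24, 0.000171), with adjusted p = 0.27, 0.74, 0.38 and 0.31 with an estimated correlation. Moderate replicate 3, without which the mPFC call against room air was lost (adjusted p = 0.12), was not left out of these 4 tests. Ribosomal proteins fell in RTN (median -0.32, 26 of 26 negative, 23 passing adjusted over the list alone, adjusted p = 8.08e-28, and adjusted p = 0.13 with an estimated correlation). In mPFC, fibroblast markers of meninges and vessels rose (median 0.77, 11 of 11 positive, adjusted p = 0.00264) and neuron markers fell (-0.23, 12 of 12 negative, adjusted p = 0.000101), both with adjusted p = 0.62 with an estimated correlation. LY96, a partner of the endotoxin receptor chosen after its values were seen, had the smallest adjusted p, 0.077, in VRC (log2 -1.77 ± 0.29; 2.74 ± 1.14 to 0.803 ± 0.155 CPM, SD, n = 6). Between the 2 conditions edgeR called 0 genes in each region, with 725, 620, 2375 and 1620 at an unadjusted p under 0.05 in mPFC, NTS, VRC and RTN. DESeq2 called 0, 1, 280 and 136 there, and limma with quality weights 35 in VRC and 0 in the others. In NTS the count at an unadjusted p under 0.05 was 981 without room air replicate 1 and 1259 in limma with quality weights, in place of 620.

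Both hypercapnia groups of a region were compared with the same 6 room air libraries, which ties their fold changes together. Across genes, which are not independent replicates, r between the mild and moderate log2 fold changes was 0.33 in mPFC, 0.66 in NTS, 0.27 in VRC and 0.46 in RTN. Simulated unchanged groups that shared controls, also simulated, gave 0.51, 0.49, 0.50 and 0.50. Genes were drawn independently there, so a real control library apart from its group has no part in these values. The covariances were 0.018, 0.064, 0.022 and 0.033, beside simulated 0.038, 0.031, 0.033 and 0.029. The spread of the real room air libraries gives 0.033, 0.039, 0.03 and 0.026. With the controls split into 3 and 3, r was -0.15, 0.21, -0.06 and 0.08. In each region edgeR called 0 genes in both comparisons, where n1×n2/N is also 0, with 73, 338, 105 and 185 genes at an unadjusted p under 0.05 in both.

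Whether the response differed among the 4 regions was tested on 16372 genes. For mild hypercapnia edgeR called 0, with 393 at an unadjusted p under 0.05, and DESeq2 called 0. TNFSF15, DNA2, SWT1 and KCTD5 were among the 5 genes of smallest p, each with an adjusted p of 1. KCTD5 had log2 fold changes of 0.38 ± 0.10 in RTN and -0.11 ± 0.10 in mPFC. For moderate hypercapnia edgeR again called 0, with 627 at an unadjusted p under 0.05, and DESeq2 0. The 5 genes of smallest p were MMP12, MYO5C, KCTD5, ERC2 and CHAD, with adjusted p = 1. ERC2, a protein of the presynaptic active zone, had 0.48 ± 0.16 in NTS and -0.49 ± 0.17 in RTN. These tests take the 72 libraries as independent, though same-numbered libraries appear to share an animal. With the replicate of each condition as a block edgeR called 0 in both. At an unadjusted p under 0.05 there were 770 and 1254, and the smallest adjusted p was 0.102 for mild and 0.648 for moderate. The differences between regions described above are thus not shown to be differences in response.

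**Figure D3:**
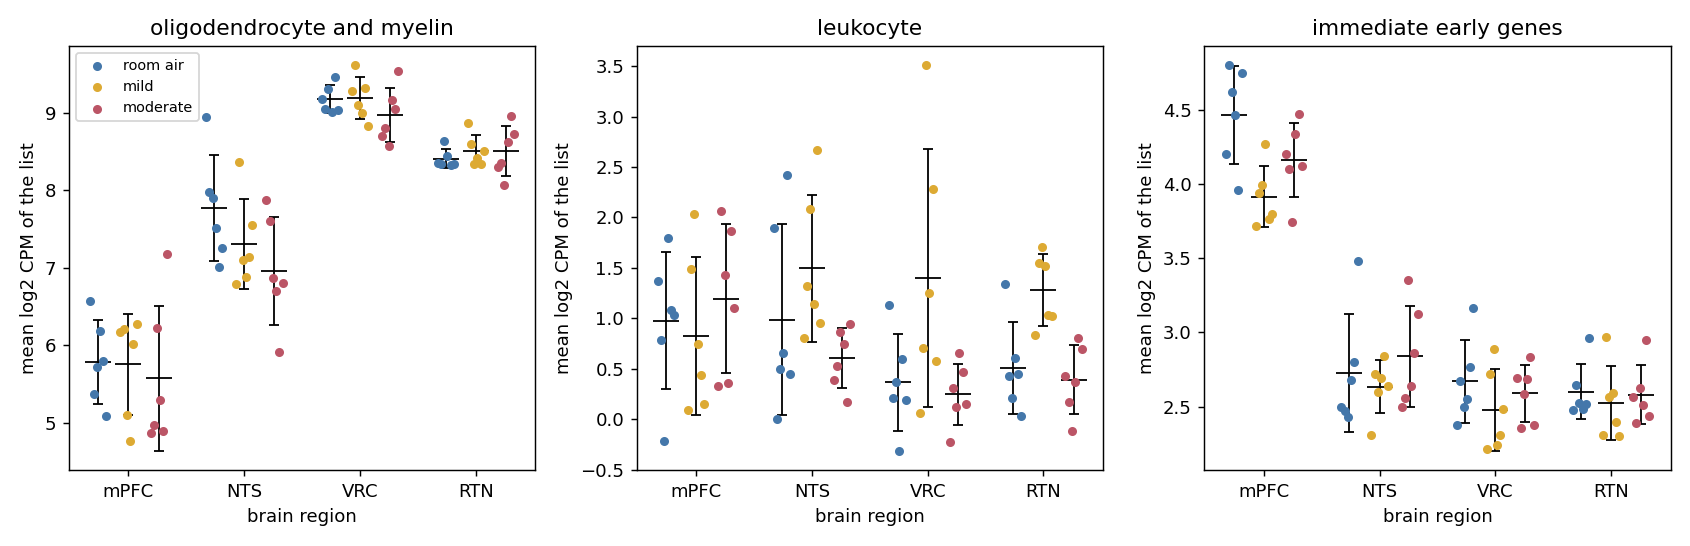
Mean log2 CPM of the myelin, leukocyte and immediate early gene lists (vertical axes) per library, by region and condition; black bars are group means with SD. Room air and moderate NTS libraries spread widely in the myelin score, with SDs of 0.68 and 0.70.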

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

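The tests of explanations in this part were chosen after the results they address had been seen, and 1 of them, the correlation with the within-group myelin slope, had its bounds set before its value was computed, though after the effect of the myelin covariate was known. The search for libraries apart from their group was run over 180 groups of 6 libraries, on library totals, list scores and genes. A library was counted as apart when its gap to the nearest other, divided by the range of its group, exceeded Dixon's 95% critical value for 6. For normally distributed values chance gives this in about 1 in 20 groups, which is 9 of 180, and 24 were found. Genes were searched as CPM without a logarithm, where that share need not hold. The 24 beside 9 thus do not show an excess of libraries apart. The scores and genes searched had been chosen after their values were seen.

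The total of VRC moderate replicate 2 was 14.08 M counts, where the other 5 ran from 20.05 to 21.08. In mean log2 CPM, the myelin score of RTN room air replicate 3 was 8.64 (others 8.33 to 8.44). The neuron score was 8.67 in mPFC moderate replicate 2 (others 9.07 to 9.31) and 8.65 in RTN mild replicate 1 (others 9.21 to 9.47). Room air replicate 6 stood above its group in the immediate early gene score in NTS (3.48, others 2.43 to 2.80) and RTN (2.96, others 2.48 to 2.64). The antigen presentation score of VRC room air replicate 1 was 4.45 (others 3.43 to 3.78).

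Single genes set other libraries apart, in CPM. APOLD1 was at 19.5 in NTS (others 2.4 to 6.18) and 24.3 in RTN (others 3.04 to 10.6), both in room air replicate 6. FKBP5 was high in moderate replicate 3 in mPFC (82.9, others 15.7 to 25.4), VRC (103, others 8.46 to 28) and RTN (118, others 20 to 31.6). THSD1 was at 27 in mPFC mild replicate 3 (others 14.1 to 18), 25.3 in mPFC moderate replicate 2 (others 11.5 to 14.7) and 34.2 in RTN moderate replicate 5 (others 11.9 to 19.5). VEGFA was at 16 in VRC mild replicate 3 (others 25.5 to 31) and 36.4 in VRC moderate replicate 3 (others 21.3 to 26.9). KCNJ10 was at 53.8 in mPFC room air replicate 2 (others 41.8 to 45.4) and 22.3 in mPFC moderate replicate 5 (others 37.2 to 42.4). MS4A7, a macrophage gene, was at 55.9 in mPFC mild replicate 3 (others 8.01 to 22.7) and 27.8 in RTN moderate replicate 5 (others 8.08 to 12.6). IL20RB was at 2.88 in mPFC mild replicate 5 (others 0.269 to 0.919) and 2.26 in mPFC moderate replicate 6 (others 0.126 to 0.686), and CD4 at 17.6 in VRC mild replicate 3 (others 0.467 to 3.99).

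APOLD1 was lower under mild hypercapnia in each region, by -2.18 in log2 over the means of 6 animals (exact p = 0.0022, the smallest that 924 splits can give, for a gene chosen for this difference; SD 0.92 in room air and 0.44 in mild). Fewer endothelial cells would lower the endothelium list with it, yet the lowest of the 4 medians of that list was -0.06. Over the 15 ways to leave out 2 room air animals the difference lay between -1.67 and -2.58, so its size did not rest on 2 animals with high APOLD1. Room air and mild animals did not overlap in this gene, which was chosen for its difference. Leaving some out could thus not have turned the sign. A different state of activity in the minutes before death stays open, since r of APOLD1 with the immediate early gene score was 0.89 over the 6 room air animals (exact p = 0.026, 0.078 after correction for the 3 relations computed; 0.56 without the 2 farthest). It was 0.52 over the mild (exact p = 0.29; -0.35 without the 2 farthest) and 0.26 over the moderate animals (exact p = 0.65; -0.55). So few animals leave that explanation and an effect of CO2 on the vessels, which was not tested, unresolved.

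Myelin markers were lower in NTS after moderate hypercapnia, with a score difference of -0.80 (exact p = 0.069, n = 6, SD 0.68 in room air and 0.70 in moderate). One room air library rich in myelin transcripts, replicate 1, was part of it: without that library the median was -0.52 in place of -0.88, and the list kept its call at the preset correlation (adjusted p = 9.4e-05), though with all libraries it was not called with an estimated correlation (adjusted p = 0.51). Punches that took a different share of white matter may explain much of the comparison, since with the myelin score as a covariate 531 genes had an unadjusted p under 0.05 in place of 2073, where chance gives 771. A different mix of white and grey matter in the libraries would also move other genes along the axis seen within groups, and over 15407 genes outside the list r was -0.66 with the within-group slope (-0.56 for mild). A loss of myelin under CO2 would give the same values, so biology and dissection are not separated here.

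Immune cell markers were higher in VRC and RTN after mild hypercapnia at the preset correlation, and with an estimated one 0 lists were called in either region (smallest adjusted p = 0.24 in VRC and 0.14 in RTN). In VRC a single animal, mild replicate 3, carried part of it: without it 2 of 5 called immune lists kept their call and the leukocyte median was 0.54 in place of 1.42 (exact p = 0.095 for the score with all 6). In RTN 4 of 4 lists kept their call without that animal, so it did not carry these calls alone, and the medians were 0.47 in place of 0.60 for leukocytes, 0.34 in place of 0.36 for microglia, 0.25 in place of 0.41 for antigen presentation and 0.26 in place of 0.21 for cytokines (exact p = 0.013, 0.054, 0.11 and 0.19 for the scores with all 6). Blood left in the tissue stays open: the globin gene HBAI had a log2 fold change of at most 0.36 in the 2 regions (0.36 ± 0.40 in VRC, SE), and its level of 2.58 ± 1.31 CPM in room air VRC is too low to decide, and an immune response to CO2 was not tested apart from these.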

How the results depend on the processing

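The fits without single libraries and edgeR's newer form of the quasi-likelihood fit were chosen after the data had been seen; the other alternatives were planned. Under alternatives, named genes kept their direction and side of the threshold in 1859 cases. They kept direction and newly passed it in 11, and kept direction but no longer passed it in 6, all 6 for THSD1. The threshold here is an adjusted p under 0.05 over all genes. Of the named genes only THSD1 passed it as reported, so most of the 1859 cases are uncalled genes that stayed uncalled. Passes adjusted over the list alone were not tested again under the alternatives. Called lists stayed called in 355 cases, lost their call in 153 and changed direction in 2. Counts stayed within 1.5 times the reported count in 149 cases and moved further in 35.

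DESeq2 called more genes than the 0 or 1 reported: mPFC mild 3, NTS mild 5, NTS moderate 22, VRC mild 27, VRC moderate 10, RTN mild 17 and RTN moderate 27, and for moderate against mild 1 in NTS, 280 in VRC and 136 in RTN. It also made more false calls on simulated data (20 to 37, and edgeR 4 to 12). Those data held changed genes and were drawn with edgeR's estimates of spread. The false calls thus do not tell how many of the real DESeq2 calls are false. On the same data DESeq2 called more of the genes changed 1.5-fold (40.3% to 65.7%, and edgeR 29.9% to 55.2%). Limma with quality weights called 3 in NTS moderate, 2 in VRC mild, 1 in RTN mild and 35 in VRC moderate against mild. A fit with the 2 groups only called 1 in VRC mild, 1 in VRC moderate and 0 in NTS moderate. The cause of these differences was not tested.

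The 1 call in NTS moderate, THSD1, became 0 with the replicate number as a block, with the myelin score as a covariate, in the newer quasi-likelihood fit, without NTS room air replicate 1 and without NTS moderate replicate 3. Its log2 fold change ran from -0.66 to -0.78 over all alternatives and its adjusted p from 7.1e-06 with DESeq2 to 0.57 with the covariate. With that covariate RTN moderate had 3 calls.

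Lists depended most on the correlation among members. With an estimated correlation 1 list was called in mPFC mild and 0 in mPFC moderate, NTS mild, NTS moderate, VRC mild, VRC moderate, RTN mild and RTN moderate, because camera then widens the error of lists whose members vary together. With the myelin score as a covariate 3 lists were called in NTS mild, 5 in NTS moderate and 13 in VRC moderate, in place of 8, 11 and 18. Cholesterol synthesis in NTS moderate reversed with it (adjusted p = 0.86). The replicate block ended 2 list calls, with 12 lists in place of 14 in VRC mild. With that block more lists were called in mPFC moderate (10 in place of 8) and NTS mild (12 in place of 8). The same held in NTS moderate (13 in place of 11) and VRC moderate (19 in place of 18). RLE factors ended 1 list call, with 7 in place of 8 in mPFC moderate. Leaving out single libraries gave 5 to 12 lists in mPFC mild and 8 to 12 in VRC mild. Ribosomal proteins in NTS mild had an adjusted p from 0.0034 without NTS mild replicate 3 to 0.43 without NTS room air replicate 1, where their direction reversed. The cause was not tested.

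Depth left 15302 to 15418 of 21343 genes per region with enough counts to test. On simulated data of the same depth edgeR called 29.9% to 55.2% of genes changed 1.5-fold, so smaller changes are mostly out of reach with 6 animals per group. The simulated genes varied independently, with no library apart. The share in the real libraries may thus be lower, and larger changes may be missed too.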

Other observations

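All tests in this part, the counts over other splits included, were chosen or bounded after the results had been seen. The values per animal take the replicate number as an animal, as the correlations across regions allow.

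The genes named here were chosen after their values were seen. Per animal, as a mean over regions (n = 6, exact tests over 924 splits), DLL4, a Notch ligand of vessel tips, differed by -0.70 under mild (exact p = 0.0043) and -0.86 under moderate hypercapnia (exact p = 0.0043). These p values do not account for the choice of the genes from 14741 and so describe the genes without testing them. APOLD1 differed by -1.58 under moderate hypercapnia (exact p = 0.0065). ANGPTL4 differed by 0.29 (exact p = 0.022) and 0.52 (exact p = 0.0022), VEGFA by -0.39 (exact p = 0.019) and -0.45 (exact p = 0.0043), and the macrophage gene MS4A7 by 1.13 (exact p = 0.0043) and 0.62 (exact p = 0.032), mild first. FKBP5 differed by 0.99 under moderate (exact p = 0.0043; SD 0.36 in room air and 0.91 in moderate) and 0.22 under mild hypercapnia (exact p = 0.44). Moderate replicate 3 held 82.9, 103 and 118 CPM of FKBP5 in mPFC, VRC and RTN, where the other moderate libraries held at most 31.6, and the difference without it was not computed. Of 40 list scores per animal, 1 had an exact p under 0.05 in each comparison, with smallest corrected p of 0.80 for mild and 0.89 for moderate. Immediate early genes differed by -0.24 per animal under mild hypercapnia (exact p = 0.05, corrected p = 0.8).

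Genes at an unadjusted p under 0.05 with the same direction in all 4 regions were counted with limma on log2 CPM, in place of edgeR. Of 14741 genes this gave 19 for mild and 23 for moderate hypercapnia. APOLD1, DLL4, NOTCH1, CCL14, RNF141 and SH2D4B were in both sets. Over splits of the animals, 11 of 100 gave as many for mild (highest other 43), so chance is not excluded, and 2 of 100 for moderate (highest other 23, as many as the real count). Over at least 3 regions the counts were 52 for mild, with as many in 31 of 100 splits (highest other 186), and 88 for moderate, with as many in 7 of 100 (highest other 135). The share under 0.05 for moderate over 4 regions is 1 of many such counts and the wider count does not share it, so it is weak evidence against chance. For APOLD1 alone 1 of 462 splits of the 12 animals, the real one, gave a difference as large (highest other 2 in log2). Since APOLD1 was chosen for this difference from all the genes tested, that count cannot exclude chance.

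Other splits of the libraries, 45 per comparison with the real one included, were counted with edgeR for genes and camera for lists. In mPFC, as many genes at an unadjusted p under 0.05 came from 30 splits for mild (532, highest other 1899), 38 for moderate (324, 1855) and 22 for moderate against mild (725, 3152). As many lists came from 36 (6, highest other 18), 25 (8, 20) and 7 (16, 18). In NTS the genes gave 24 for mild (718, 3036), 7 for moderate (2073, 4115) and 19 for moderate against mild (620, 1548), and the lists 40 (8, 19), 24 (11, 21) and 23 (9, 18). The 1 gene called in NTS moderate was matched by 3 splits, the highest with 1062 calls. Chance is excluded in none of these.

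In VRC the genes gave 12 splits for mild (953, highest other 1757), 15 for moderate (867, 2587) and 6 for moderate against mild (2375, 3484). The lists gave 11 (14, 19), 1 (18, 16) and 3 (20, 20), so the 18 lists of VRC moderate were matched by no other split. Chance gives a share under 0.05 in about 1 of 20 such counts, and these lists were called at the preset correlation, with 0 at an estimated one, so this count alone is weak evidence against chance. It is not excluded for the others. In RTN the genes gave 5 (1011, 1329), 8 (1132, 2033) and 7 (1620, 4158), and the lists 8 (11, 14), 24 (9, 14) and 14 (12, 18), with chance not excluded. For differences among regions 7 of 25 splits gave as many genes for mild (393, highest other 840) and 10 of 25 for moderate (627, 1698). Splits that call many genes at an adjusted p under 0.05, 1062 in NTS where the real moderate split called 1 and 1507 in RTN where moderate against mild called 0 (1620 at an unadjusted p under 0.05 with edgeR, and 136 called by DESeq2 and 0 by limma), point to a structure of the samples other than the CO2 groups in those splits. The median over the other splits was 0 such calls in both, and the source was not tested.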
